A study of Homo sapiens with 2 samples.

How the data were processed

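Gene expression was measured on 2 Illumina bead arrays, on which each transcript is read by a probe carried on many beads. Both arrays held total RNA from BL2, a cell line derived from a Burkitt's lymphoma, a tumour of germinal centre B cells. The cells had been infected with a lentivirus and then selected with puromycin, per the labels' protocols. Such a virus inserts DNA that encodes a short hairpin RNA into the genome, so that a chosen mRNA is degraded. Each group had 1 array, so no SD, SE or p-value between groups could be computed, and every difference compares these 2 arrays without a check on replicate error. Per the labels' protocols, lower IRF4 was established by quantitative PCR before the arrays were run, and the hairpin identifier given there lies outside the range of identifiers it lists. The multiplicity of infection of the cells on the arrays is not given in the sources used here.

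The labels of the arrays contradict each other. One sample is titled shIRF4 and the other Cont, but the infection label of the first names a control hairpin and that of the second a hairpin against IRF5, a gene the series' design text does not mention. Groups were taken from the titles before the data were examined, and the samples are called the array titled shIRF4 and the array titled Cont. Differences are given as titled shIRF4 minus titled Cont, and under the infection labels every sign would turn.

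The main table holds intensity values that the authors deposited as non-normalized. These are linear probe intensities with lowest values of 35.9 and 36.4. Probes with a detection p near 0.5 had median intensities of 49.7 and 51.6, so the values still held background. Beside them stands a detection p-value per probe and array, per the file headers, whose steps match 645 negative control probes on the array titled shIRF4 and 644 on the array titled Cont. A second deposited table holds intensity values that were quantile normalized by the authors: both of its columns have the same sorted values, and each has a rank correlation of 1 with its own array in the first table. Its median of 47.2 lies below the medians of the first table (60.5 and 63.9). Its values are linear, and which arrays entered that normalization and how background was treated stay unknown. The software for scanning and normalization is not given in the sources used here. Columns were matched to samples through the sample descriptions, and no other column of sample values was present (0 columns).

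The non-normalized intensities were processed with neqc of limma 3.58.1 in R 4.3.3. This step fits the background from the detection p-values (normexp), adds an offset of 16, quantile normalizes the arrays and takes log2. The offset pulls the differences of dim probes towards 0. Of 24531 probes, 23267 had 1 gene symbol in the platform annotation, 0 had several and 1264 were unnamed here. The reference gene table (GRCh38.p14) held the gene ID of 23143 probes, and it changed 0 symbols. It was used for names and gene order only, because no genome build is named for the arrays, and no coordinates are printed. The named probes covered 17553 genes, and each gene was represented by its probe with the highest mean log2 signal. A gene was called detected at a detection p under 0.01, and 9780 genes were detected in at least 1 array. Listed genes without a named probe, among them 11 of 15 immunoglobulin genes, were not analysed here.

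At a detection p under 0.01, 11750 probes (47.9%) were above background on the array titled shIRF4 and 12008 (49.0%) on the array titled Cont. The brightest probe read 22891. The number of arrays limits the precision. As a stand-in for replicate error, the SD of log2 differences was taken over the 978 genes of like signal, in 10 equal bins by mean signal. This SD was 0.51 in the bin where it was largest and 0.28 in the brightest bin, and it holds real differences between the arrays as well as noise. A second gauge came from 1460 genes with 2 probes detected in both arrays, whose log2 differences were 0.19 apart in the median and 0.64 at the 95th percentile, with a correlation of 0.61 across genes. Both probes of a gene read the same RNA on the same arrays, so this second gauge leaves out error from cultures and RNA preparation. Genes are not independent replicates.

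A gene measured in only 1 array has a bound in the other. For these genes the fold is given as "at least N-fold", the bright value against the higher of the lowest signal among detected probes of the dim array (log2 4.87 for titled shIRF4 and 4.81 for titled Cont) and the probe's own value. Genes were counted by a rule of size, a difference of at least 2-fold. Before the data were examined, 24 gene lists were fixed. For each, the median log2 difference of the detected members was set against 10000 random lists of the same size, matched by bin of mean signal, and members at least 1.5-fold apart were counted. Genes with related functions vary together, so random lists spread less than real ones would, and the percentiles describe these 2 arrays and are not p-values. Percentiles under alternative settings used 1000 random lists. About 1.2 of 24 lists would lie outside the central 95% by chance if genes were independent.

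Genes named in the text were chosen by a rule fixed before the data were examined: IRF4 and IRF5, the 12 largest differences on each side among genes detected in both arrays, the 5 largest bounds on each side, and the 4 largest differences of each list (6 for B-cell receptor signalling, MHC class I, MHC class II and the germinal centre programme). Genes named outside this rule were chosen after their values were seen: TRIM5, MYBL2, CD83, CIITA, CD74, CD80, CD86, B2M, CD79A, CD79B, PRDM1, XBP1, PARP9, IFIH1, RIGI and those of the closing section. The alternatives were median scaling, cyclic loess, no background correction, an offset of 50, the authors' value table, 3 other detection filters, the mean over probes, size rules of 1.5-fold and 3-fold, and the groups of the infection labels.

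The steps were tested on simulated data before use. A pair of arrays was drawn from the signal of the array titled Cont, with an assumed noise of 0.15 (SD, log2) and 200 of 10410 genes changed. Of the genes made 4-fold and 3-fold higher, 100% and 90% were counted at 2-fold. For genes made 4-fold and 3-fold lower the shares were 82% and 78%, and 0.03% of 10210 unchanged genes were counted. The simulated pair held no variation between cultures, infections or RNA preparations. Its assumed noise lies below the SDs of 0.28 to 0.51 seen between the real arrays. The 0.03% is thus no error rate for the real comparison. Of 20 simulated lists of unchanged genes, 1 lay outside the central 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.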

Results

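Transcripts of BL2 Burkitt's lymphoma cells were profiled after lentiviral infection, with 1 array in each group and no replicates. The sample titles name a hairpin against IRF4 and a control, while the infection labels name a control and a hairpin against IRF5. IRF4 is a transcription factor of the interferon regulatory factor family that acts in B-cell activation and plasma cell differentiation. By the sample titles, the comparison asks which genes differ when IRF4 is reduced. The series' title points to B-cell receptor signalling, antigen presentation and germinal centre genes. The arrays were of like brightness, with mean intensities of 388.7 (titled shIRF4) and 425.9 (titled Cont). Their rank correlation over all probes was 0.924.

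IRF4 itself was lower in the array titled shIRF4. Its 1 probe, designed on transcript NM_002460.1, read an intensity of 131 there and 323 in the array titled Cont. After normalization the log2 signals were 6.73 and 8.04, a difference of -1.31, or 59.6% lower. Among the 978 genes of like signal it was the 6th lowest difference, at 3.3 times their SD of 0.39. IRF5, which the infection label of the other array names, differed by 0.00 (log2 5.91 in both) in its 1 probe. The direction of the IRF4 difference is that of the titles, and under the infection labels its sign would be the opposite. Across 6 processing alternatives the IRF4 difference ran from -1.32 to -0.98.

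Few genes differed by a large amount. Of 8842 genes detected in both arrays, 72 were at least 2-fold higher and 86 at least 2-fold lower in the array titled shIRF4. A further 12 genes higher and 6 lower were detected in 1 array only and had a bound of 2-fold or more. Taken by normalized values over all 9780 genes detected in at least 1 array, the counts were 93 higher and 103 lower. The median difference was 0.01 and the SD 0.40 on the log2 scale. In the authors' value table the counts were 35 and 36, all of them among the same 93 and 103 genes. Of 22 genes at least 2-fold apart that had a second probe detected in both arrays, the second probe went the same way in 21 and by at least 2-fold in 10. The exception was TRIM5, at -1.07 in its brightest probe and 0.15 in the second.

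Among genes detected in both arrays, the one farthest lower in the array titled shIRF4 was GSDME (log2 difference -2.18), a gasdermin that forms membrane pores when cleaved by caspase-3. It was followed by CENPF (-2.14), a kinetochore protein of dividing cells, and CREB5 (-2.13), a transcription factor. LTA, the cytokine lymphotoxin alpha, differed by -2.04, VPREB3, a B-lineage protein related to the surrogate light chain, by -1.80, and CR2, the complement receptor CD21 of the B-cell coreceptor, by -1.76. SGK1, a serine/threonine kinase, and RGS16, a regulator of G-protein signalling, differed by -1.81 and -1.68. MYL2 (-1.99), ZNF518B (-1.85), STAG3L3 (-1.72) and TESK2 (-1.61) complete the 12 largest. STAG3L3 belongs to a family of near-identical copies that a probe may not tell apart. Of genes below detection in the array titled shIRF4, GSPT2 was at least 7.58-fold lower, ZIC2 at least 5.24-fold, GNG11 at least 3.07-fold, RAB18 at least 2.10-fold and ZNF671 at least 2.09-fold.

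Of the genes detected in both arrays, ABCB9, a lysosomal peptide transporter related to TAP, was the farthest higher in the array titled shIRF4 (log2 difference 2.71, and 2.60 in its second probe). IFITM2, an interferon-induced transmembrane protein, differed by 2.66, RNF144A, an E3 ubiquitin ligase, by 2.48, and TGFBR3, the TGF-beta coreceptor betaglycan, by 2.45. LYSMD2 (2.31), RAMP1 (2.22), a receptor activity-modifying protein, and BHLHE40 (1.74), a helix-loop-helix repressor, came next. POU4F1 and SOCS2, a suppressor of cytokine signalling, both differed by 1.73. GPER1 (1.70, and 2.00 in its second probe), RAB37 (1.67, and 1.08 in its second probe) and SUB1 (1.64) complete the 12 largest. Of genes below detection in the array titled Cont, PLAC8 was at least 8.61-fold higher, TRPM4 at least 4.33-fold, RXRA, the retinoid X receptor alpha, at least 2.96-fold and LY6E at least 2.78-fold. MLKL, an effector of necroptosis, was at least 3.72-fold higher in its brighter probe, while its other probe differed by 0.56.

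**Figure D1:**
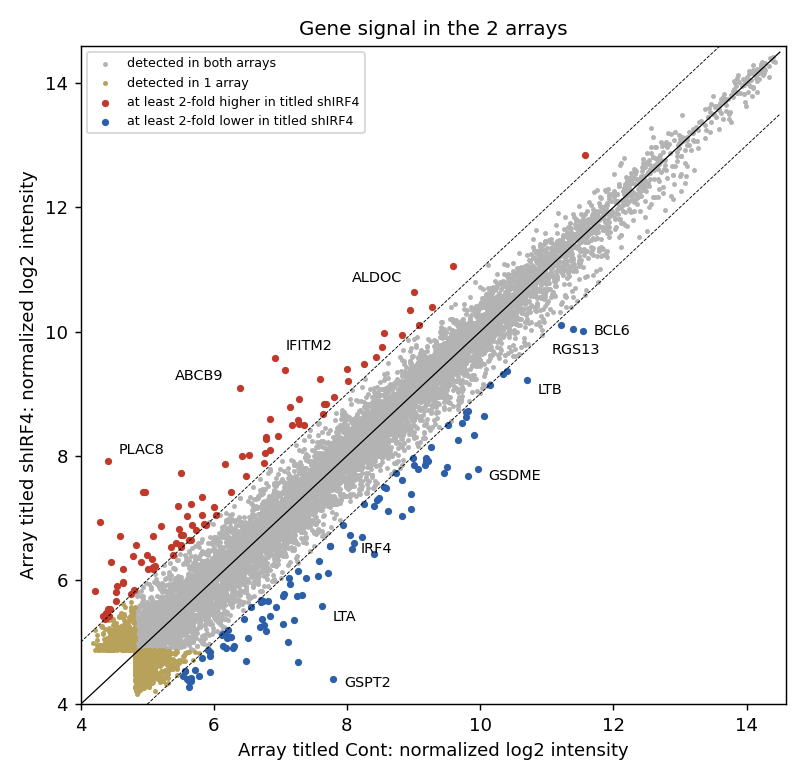
Normalized log2 intensity of 9780 genes in the array titled Cont (horizontal axis) and the array titled shIRF4 (vertical axis), 1 point per gene, with the line of equality and dashed lines at 2-fold. The 93 genes higher (red) and 103 lower (blue) in the array titled shIRF4 lie outside the dashed lines, with IRF4 among the lower ones.

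Germinal centre genes were lower as a group in the array titled shIRF4. Of 27 detected members of the list, 8 were at least 1.5-fold lower, 0 were at least 1.5-fold higher and 19 lay between. The median log2 difference was -0.23, at percentile 0.0 of random lists, whose central 95% ran from -0.12 to 0.14. BCL6, a transcriptional repressor and the master regulator of the germinal centre programme, was lower by a log2 difference of -1.53, from a signal of 11.54 to 10.01. RGS13, a G-protein regulator of germinal centre B cells, differed by -1.36, the DNA glycosylase NEIL1 by -1.28, the surface enzyme CD38 by -0.80 and the adaptor STAP1 by -0.66. FAS, the death receptor CD95, differed by -1.13 in its brighter probe and by 0.30 in the other. MYBL2 and CD83, both at 0.46, were the members farthest above 0, and 9 members in all lay above it.

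MHC class II genes also lay lower. Of 24 detected members, 5 were at least 1.5-fold lower and 0 higher, 1 of the 5 (HLA-DRB5) being below detection in the array titled shIRF4. The median was -0.21, at percentile 0.2. The median was -0.17 with the 2 members detected in 1 array at their bounds. LGMN, the lysosomal protease legumain, differed by -1.31 and by -1.27 in its second probe. HLA-DOB and HLA-DMB, which edit peptide loading, differed by -0.84 and -0.60, and HLA-DPB1, a classical beta chain, by -0.77. HLA-DRB5 (-0.59) and HLA-DQA2 (-0.57) were detected only in the array titled Cont. HLA-DRB5 had no bound above 1-fold, and HLA-DQA2 was at least 1.32-fold lower. The class II transactivator CIITA differed by -0.23 and the invariant chain CD74 by -0.14 (-0.46 in the lowest of its 3 probes). The costimulatory genes CD80 (0.53) and CD86 (0.54, and 0.05 in the lowest of its 3 probes) lay above 0. Probes of HLA genes may bind transcripts of related loci and depend on the allele the cells carry.

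MHC class I processing genes did not stand apart as a group. Of 18 detected members, 3 were at least 1.5-fold lower and 0 higher, and the median of -0.11 lay at percentile 7.8. TAP2, a subunit of the peptide transporter, differed by -1.20 in its brighter probe but by -0.05 in its other. The aminopeptidase ERAP2 differed by -0.72 and the immunoproteasome subunit PSMB9 by -0.64 (-1.08 in its second probe). The class I transactivator NLRC5 differed by -0.55, TAP1 by -0.43 and HLA-G by -0.41. B2M, the shared light chain, differed by 0.05. With the mean over all probes of a gene the list median was -0.19, at percentile 0.9.

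B-cell receptor signalling genes differed little as a group. Of 36 detected members, 3 were at least 1.5-fold lower, 1 was higher and 32 lay between. The median of -0.14 lay at percentile 0.8. It was -0.13, at percentile 1.3, with detection in both arrays, and -0.06, at percentile 9.6, with the mean over probes. With the 3 members detected in 1 array at their bounds the median was -0.09. The random lists (-0.11 to 0.13) held no bounds, so they do not gauge that value. The lower members were CR2 (-1.76), the inhibitory receptor CD22 (-1.18) and the exchange factor VAV1 (-0.68). SYK, a kinase of the first steps of the cascade, was higher by 0.68, and BCL10, an adaptor to NF-kappaB, differed by 0.54. FOS (-0.58) was detected only in the array titled Cont and had no bound above 1-fold. The receptor chains CD79A and CD79B differed by -0.35 and 0.04.

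**Figure D2:**
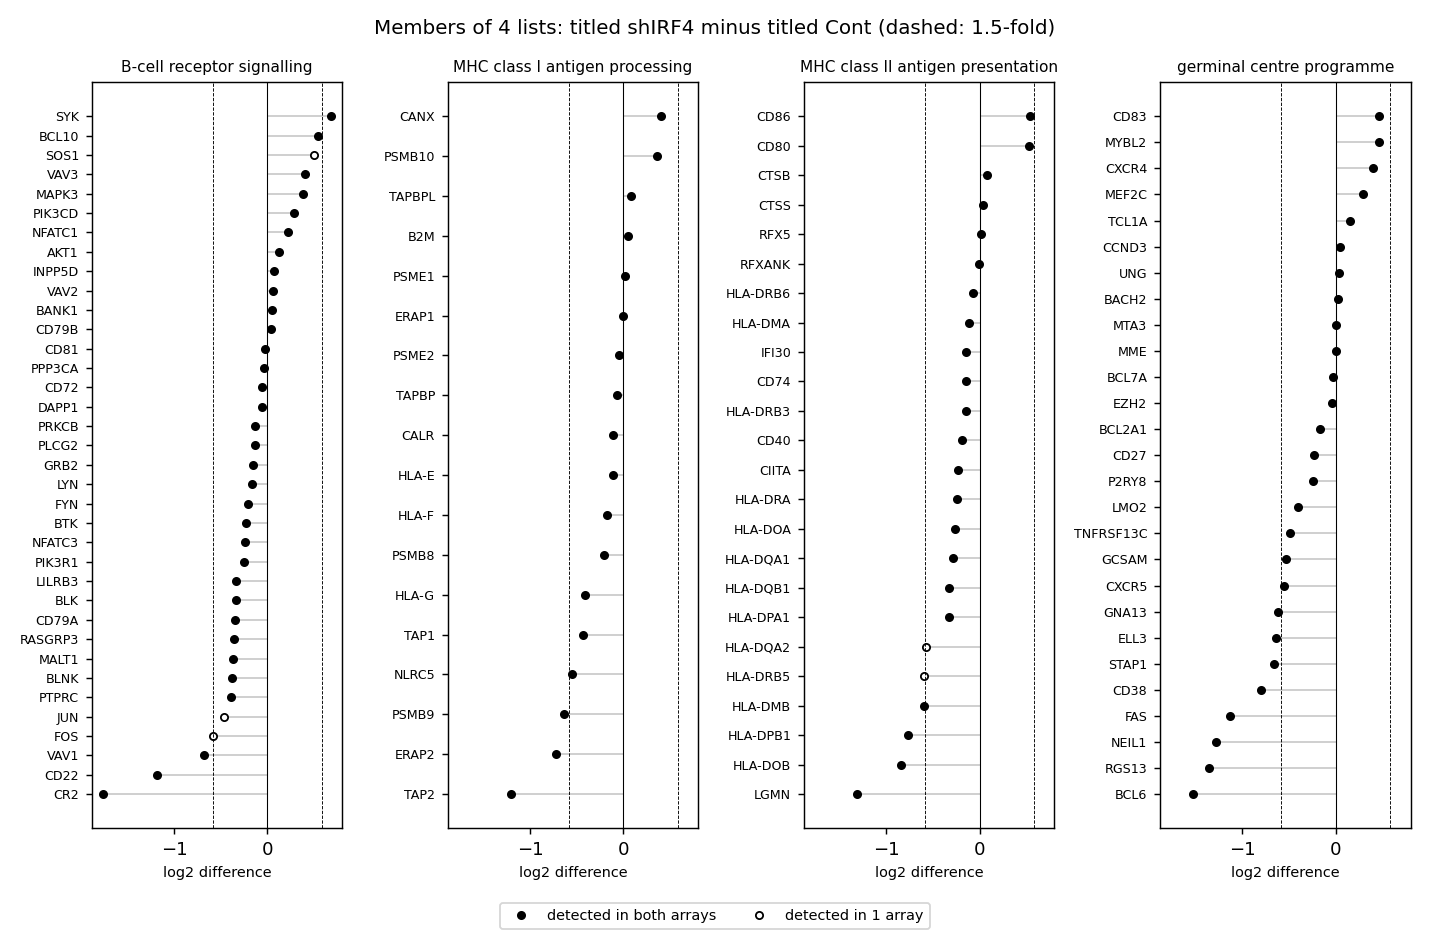
Log2 difference (titled shIRF4 minus titled Cont) of each detected member of 4 fixed lists, 1 point per gene, with filled points for genes detected in both arrays, open points for genes detected in 1 array and dashed lines at 1.5-fold. The germinal centre list reaches down to BCL6 at -1.53 and has 8 members beyond the lower line and 0 beyond the upper one.

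The plasma cell list was mixed. Of 16 detected members, 5 were at least 1.5-fold lower and 2 higher, with a median of -0.15 at percentile 4.0. That median ran from -0.26 with the mean over probes to -0.01 with a detection p under 0.05, at percentiles 0.6 and 38.9. EAF2, an elongation factor partner, differed by -1.12, TENT5C, a poly(A) polymerase, by -0.89, TXNDC5, an ER thioredoxin, by -0.74 and CREB3L2 by -0.73. PRDM1 (Blimp-1) and XBP1, drivers of plasma cell differentiation, differed by 0.70 and 0.65, but a second PRDM1 probe differed by 0.06. Of 21 B-cell transcription factors, SPIB, an ETS factor, was lower by a log2 difference of -1.11. The Ikaros family members IKZF3 and IKZF1 differed by 0.69 and 0.57 and KLF2 by 0.69, and the median of 0.06 lay at percentile 71.1. Within the IRF family, IRF8 differed by -0.78, IRF9 by -0.54, IRF7 by -0.31 (0.49 in its other probe) and IRF1 by 0.74, with a median of -0.15 over 6 genes at percentile 14.2, which turned to 0.05 with the mean over probes. Among 4 immunoglobulin-related genes only VPREB3 was beyond 1.5-fold, IGLL3P, VPREB1 and IGLL1 differed by 0.18, -0.14 and -0.04, and the median of -0.09 lay at percentile 25.6.

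Type I interferon response genes were lower, with a median of -0.33 over 14 detected members at percentile 0.1. Of these, 3 were at least 1.5-fold lower and 0 higher, and 3 lay above 0, IFIH1 (0.21), RIGI (0.15) and PARP9, which was below detection in the array titled Cont and at least 1.31-fold higher. Outside the list, the interferon-induced genes IFITM2 (2.66) and LY6E (at least 2.78-fold) were higher. OAS1, a double-stranded RNA sensor, differed by -1.52, with its 3 probes between -1.61 and -1.18. OAS2 differed by -0.82 (-0.52 in the highest of its 4 probes) and the ubiquitin-like ISG15 by -0.62, and TRIM22 by -0.52. Without a detection filter the median was -0.09. The NF-kappaB target list did not stand apart (median -0.03 over 15 members, percentile 37.1), although 3 of its cytokine genes were lower. LTA differed by -2.04, LTB by -1.48 (-1.27 in its second probe), and TNF, below detection in the array titled shIRF4, was at least 1.69-fold lower. REL, an NF-kappaB subunit, differed by -0.52.

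Cell cycle lists went opposite ways. G2/M genes had a median of -0.26 over 27 members at percentile 0.0, and 24 of them lay below 0. The difference exceeded 1.5-fold in 2 members, CENPF (-2.14) and DLGAP5 (-0.61), with CENPE at -0.53 and CCNA2 at -0.51. Without CENPF the median was -0.25. DNA replication genes had a median of 0.22 over 27 members at percentile 100.0, with 21 above 0 and 1 beyond 1.5-fold, CDC6 (0.61), a replication licensing factor. MCM5, UHRF1 and CDC45 differed by 0.48, 0.43 and 0.34. Glycolysis genes had a median of 0.25 over 18 members at percentile 99.9, with 1 beyond 1.5-fold, ALDOC (1.63), a fructose-bisphosphate aldolase. PGAM1 and GPI both differed by 0.48, and ENO2, detected only in the array titled Cont, was at least 1.36-fold lower.

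**Figure D3:**
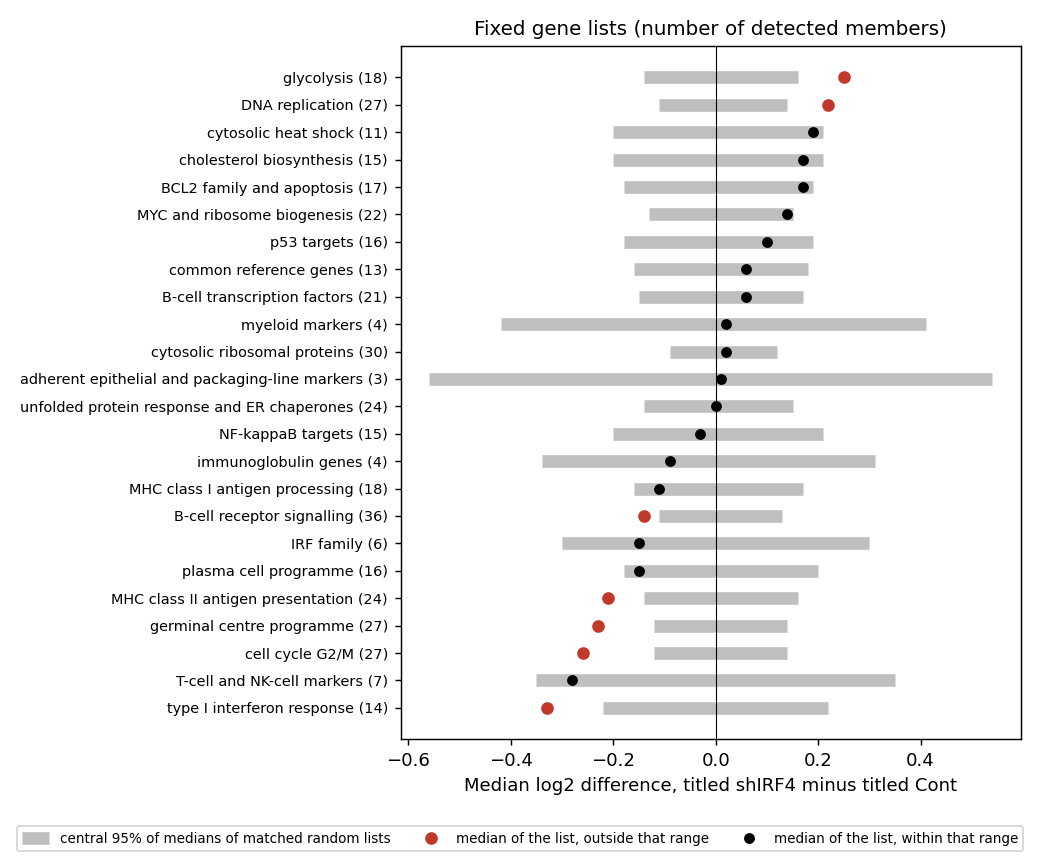
Median log2 difference (titled shIRF4 minus titled Cont) of the 24 fixed gene lists, with grey bars for the central 95% of medians of 10000 matched random lists and the number of detected members in parentheses. Red points mark the 5 lists below and 2 above their bar, from type I interferon response at -0.33 to glycolysis at 0.25.

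The remaining lists lay within the central 95% of random lists with the settings used throughout. In some of 9 alternatives a list passed its upper end: MYC and ribosome biogenesis in 5 (up to percentile 99.3), heat shock in 4 (up to 98.6), the BCL2 family in 1 (97.9) and ribosomal proteins in 1 (100.0). Stress and death genes included single members that differed more than their list. ATF3 and DDIT3, transcription factors of the stress response, differed by 1.43 and 0.98 and CHAC1 by 0.71, against EDEM1 at -0.57 and a list at percentile 40.6. SESN2, a stress-induced sestrin, differed by 1.06, with ZMAT3 at -0.78, MDM2 at -0.53 and CCNG1 at -0.46, in a p53 target list with a median of 0.10 (percentile 82.0). The BCL2 family list had a median of 0.17 (percentile 95.9), led by the BH3-only genes PMAIP1 (0.63), BCL2L11 (0.61, and 0.35 in the lowest of its 3 probes) and HRK (0.55), with MCL1 at 0.45 in 1 probe and -0.14 in the other. Heat shock genes had a median of 0.19 (percentile 96.3), with HSPA4L at 0.77, HSPA1B at 0.49, HSPB1 at 0.39 and HSPH1 at 0.31, and median scaling moved that median to 0.31. MYC and ribosome biogenesis genes had a median of 0.14 (percentile 97.2), which was 0.24 under median scaling, and 0 members beyond 1.5-fold, with SRM at 0.58, BOP1 at 0.56, RRP9 at 0.45 and PPAN at 0.42. Cholesterol synthesis genes had a median of 0.17 (percentile 93.5), with INSIG1, a regulator of sterol synthesis, at -0.89, LSS at 0.48 (1.24 in its other probe), DHCR7 at 0.46 and NSDHL at 0.41.

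Ribosomal protein genes had a median of 0.02 over 30 members (percentile 47.1), with RPL32 at 0.52, RPL6 at 0.40 and RPL13 and RPL23 at -0.26 (RPL13 at 0.45 in its other probe), and median scaling moved that median to 0.31. Common reference genes had a median of 0.06 (percentile 68.0), which was 0.18 under median scaling, with PPIA at 0.63, SDHA at 0.47, GAPDH at 0.29 and PGK1 at 0.22. Markers of other cell types were mostly below detection. Of 20 T-cell and NK-cell markers 7 were detected, with a median of -0.28 (percentile 6.2), which ran from -0.44 with detection in both arrays (percentile 1.4) to -0.07 with no filter (percentile 10.6). LCK differed by -0.58, LAT by -0.53 (0.23 in its other probe) and ZAP70 by -0.44, and NKG7, detected only in the array titled shIRF4, was at least 1.28-fold higher. Of 16 myeloid markers 4 were detected (median 0.02, percentile 52.6, and -0.35 with detection in both arrays), CD68 at -0.63, LYZ at 0.54, AIF1 at -0.35 and CD14 at least 1.19-fold higher. Of 18 markers of adherent epithelial cells, the kind of cell that packages the virus, 3 were detected (median 0.01, percentile 51.6), with CCN2 at least 1.26-fold lower, COL1A1 at 0.40 and CDH2 at 0.01.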

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

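Probes that carry no gene name here lie outside every comparison of the report and were set aside for that reason, yet some gave a signal that differed between the arrays. Of 578 such probes detected in at least 1 array, 5 were at least 2-fold higher and 4 at least 2-fold lower in the array titled shIRF4, a share of 1.56% against 2.0% of named genes. All 5 higher probes were detected in both arrays, but only 2 of the 4 lower ones were. The other 2 were below detection in the array titled shIRF4 and had bounds under 2-fold. The probe ILMN_2131523 stood first, with a log2 signal of 7.46 against 5.49 and a difference of 1.97. On the lower side ILMN_1724422, detected in both arrays, differed by -1.20, and ILMN_2193864 was at least 1.86-fold lower.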

How the results depend on the processing

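No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. Groups by the infection labels turn the IRF4 difference to 1.31 and exchange the counts of genes (103 higher and 93 lower). The counts of genes at least 2-fold higher in the array titled shIRF4 and of genes at least 2-fold lower in the array titled shIRF4 were 47 and 48 without background correction and 47 and 48 with an offset of 50. Both settings leave or add a constant that shrinks the folds of dim genes by construction. In the authors' value table they were 35 and 36, and the cause was not tested. At 1.5-fold the counts were 484 and 618, and at 3-fold 22 and 16. Under the other normalizations, filters and the mean over probes they ran from 72 to 118 higher and from 86 to 106 lower. Of 216 list medians under alternatives, 199 moved by less than 1 SD of random list medians and 17 by more, and the cause was not tested. Median scaling gave B-cell receptor signalling -0.07, the germinal centre programme -0.16, MYC and ribosome biogenesis 0.24, the unfolded protein response 0.09, heat shock 0.31, ribosomal proteins 0.31 and common reference genes 0.18, with the median of all genes at 0.07. Cyclic loess gave ribosomal proteins 0.08, and the authors' table gave the germinal centre programme -0.16. The mean over probes gave the IRF family 0.05, B-cell receptor signalling -0.06 and the plasma cell programme -0.26. A detection p under 0.05 gave the plasma cell programme -0.01, and detection in both arrays gave myeloid markers -0.35. With no filter the plasma cell programme stood at -0.03, the interferon response at -0.09 and T-cell and NK-cell markers at -0.07. Over the 9 alternatives run on lists, each against 1000 random lists, the germinal centre list stayed between percentiles 0.0 and 0.6, MHC class II between 0.1 and 0.8, interferon response between 0.0 and 2.3, G2/M at 0.0, DNA replication between 99.1 and 100.0 and glycolysis between 99.5 and 100.0. B-cell receptor signalling ranged from 0.1 to 9.6 and came within the central 95% in 1 of the 9. Lists otherwise within it left it at the lower end in 4 (plasma cell programme, down to 0.6), 1 (MHC class I, 0.9) and 1 (T-cell and NK-cell markers, 1.4). They left it at the upper end in 5 (MYC and ribosome biogenesis, up to 99.3), 4 (heat shock, up to 98.6), 1 (BCL2 family, 97.9) and 1 (ribosomal proteins, 100.0). Because no background correction and the offset of 50 gave the same list medians, these counts hold fewer than 9 independent settings. Under these 9 alternatives, which keep the groups of the titles, 0 of the genes named by the rule (other than IRF4) that were beyond 1.5-fold reversed. All 9 reprocess the same 2 arrays, so this is no check on replicate error. Of 1188 values under alternatives 82 moved by more than the SD of genes of like signal. Many of the 1188 could not move. The detection filters leave a gene's value as it is, as does the mean over probes for a gene with 1 detected probe. Of 432 member counts 47 moved by over 1.5 times. Signal over background limits dim genes: 938 genes were detected in 1 array only.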

Other observations

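The tests of the IRF4 labels and of the cell cycle lists were chosen after their results were seen, as were the genes in the next paragraph. The hypoxia and BCL6 tests were written before their lists were examined. After the values were seen, the wording of the explanation tested on new cell cycle lists was revised. A margin of 1 SD of random list medians was also added to the reading of that test and of the hypoxia and BCL6 tests, which moved the BCL6 test from excluded to open. The parts of the cell cycle gap were also separated after their values were seen, and exchanged titles, first left open under a stricter bound, are read here by the bound as written for that test. The hypoxia test, excluded by the bound written beforehand, was later left open because of the spread of its members. The matched random lists already reflect that spread in part, so the list as a set is read here by the bound written beforehand.

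LTA, TNF and LTB, which stand next to each other in the reference gene table, were all lower in the array titled shIRF4, by log2 differences of -2.04 and -1.48 for LTA and LTB and at least 1.69-fold for TNF. The inflammatory caspase CASP4 differed by -1.60. The adhesion ligand CD58 differed by -1.56 and the peptide hormone adrenomedullin, ADM, by 1.64. BATF, a transcription factor that binds DNA together with IRF4, differed by 1.36. Of 275 detected genes named ZNF with a number, 171 lay below 0, 8 were at least 2-fold lower and 0 at least 2-fold higher. Of all 9780 detected genes, 103 were at least 2-fold lower and 93 at least 2-fold higher. The set was formed because several of its members stood among the lower genes, so its counts do not test a difference.

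The lower IRF4 signal stands in the array whose infection label names a control. Exchanged titles would predict a lower IRF5 signal in the array titled Cont, and an IRF4 difference within the SD of genes of like signal. The IRF5 difference was 0.00 and that of IRF4 -1.31, at 3.3 times that SD, which argues against exchanged titles, mainly through IRF4. The IRF5 probe was dim, with intensities of 89.1 (titled shIRF4) and 101 (titled Cont) against backgrounds of 49.7 and 51.6. Its bin had the largest SD (0.51), and the offset pulls differences of dim probes towards 0, so its 0.00 weighs less. The gauge is the spread of other genes, since each group had 1 array and each gene 1 probe. The labels' protocols report lower IRF4 by quantitative PCR before the arrays were run, without naming an array, and a hairpin against IRF4 in the array titled shIRF4 stays open as the biological explanation.

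G2/M genes were lower and DNA replication genes higher in the array titled shIRF4, a gap of 0.48 between their medians. The normalization as the cause is argued against, since the smallest gap under 5 other normalizations was 0.42. Lists of G1/S and G2/M genes that had not been used before gave a gap of only 0.07, within the central 95% of random pairs (-0.22 to 0.21). The new G2/M genes had a median of -0.13, with 20 of 26 below 0 and 4 above, at percentile 2.4 and so just outside the central 95%, while the 20 new G1/S genes had a median of -0.06 at percentile 19.6. The higher part of the gap may thus belong to the replication genes first listed, and whether the lower part holds for G2/M genes at large stays open. A shift in cell cycle phase, whether from the hairpin or from the state of the 2 cultures, was not tested.

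Glycolysis genes were higher in the array titled shIRF4, and a lower oxygen supply in that culture was a candidate explanation. It was tested on hypoxia-induced genes outside the fixed lists. Over 22 detected genes the list lay at percentile 45.8, with 11 members above 0 and 11 below. The list median was -0.0, and the central range of matched random medians ran from -0.17 to 0.18. A shift as large as the glycolysis median of 0.25 would lie outside that range. This argues against low oxygen as a shift of these genes as a set. The members spread widely (SD 0.46), so a response of only some of them stays open. Of the members, 4 were at least 1.5-fold higher, PFKFB4 (1.18), P4HA2 (0.83), BNIP3 (0.73) and DDIT4 (0.64), and 1 was lower, WSB1 (-0.66), while VEGFA differed by 0.02. Other differences between the cultures and the hairpin itself were not tested.

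Because BCL6 is a repressor, a hypothesis was that genes it represses would be higher where its own signal was lower. Over 8 detected genes outside the fixed lists the median was 0.25, at percentile 96.2 and just within the central 95% of random lists (-0.26 to 0.28), so the hypothesis may or may not hold and the list is too short to decide. CXCL10 differed by 0.90 and CD69 by 0.49, against IL10 at -0.74.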
